A study of Mus musculus with 2 samples.

How the data were processed

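The series measured monomethylation of histone H3 at lysine 4 (H3K4me1), a mark of enhancers and of the flanks of active promoters, by chromatin immunoprecipitation and sequencing. The tissue was mouse forebrain at embryonic day 16.5, from mixed-sex embryos of a C57BL/6N strain, per the labels. The labels gave 1 group of 2 biological replicates. They stated that replicate 2 pooled the forebrains of 41 embryos and that replicate 1 was also a pool, without its number. With 1 group there was no condition to compare, so the comparisons were between the replicates, and between genes, regions and sequences within the tissue.

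The 4 deposited peak lists were used. Each replicate had its own list, and 2 lists covered both replicates together: a pooled list and a list of replicated peaks, which the deposited descriptions name as derived from both replicates' lists and the pooled list. Per the deposited descriptions, all lists were on the mm10 assembly. They also named replicate 1's list as derived from its alignments and 2 further files, and replicate 2's list from its alignments and 1 further file, without saying what those files were. The labels also named a possible control experiment, which was not used here. The aligner, the peak caller, its settings and the rule for a replicated peak were not given in the sources used here. The signal of a peak, called enrichment below, was the authors' value in the deposited lists, and its scale was not stated. The deposited lists also gave −log10 p and −log10 q for each peak. The lowest −log10 p was between 2.00 and 2.04 in the 4 lists, while −log10 q went down to 0.312, so every list held peaks with a q far laxer than a usual threshold. Peaks with q at most 0.05 made up 97.5% of the replicated list, 95.9% of replicate 1's and 85.5% of replicate 2's. The enrichment, p and q values are the authors' own and were used only to rank, filter or describe peaks within a list. The lists held no read counts, so the sequencing depth behind a peak was unknown, and no interval that needs counts was given.

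Peaks on unplaced sequences, 2 in replicate 1's list and 1 in the pooled list, are in the counts of peaks but in no comparison with genes, and chromosome Y, with 1 peak in replicate 1's list, was kept. Coordinates were read as mm10 and are printed counting from 1. The genome sequence was GRCm38.p6, the same build, and no peak ended past the end of a chromosome in any list. Genes were the protein-coding genes of GENCODE vM21, 21911 symbols on the autosomes, X and Y, with the gene's 5′ end as transcription start site (TSS). The replicated list was the main list. Covered length is the number of bases under at least 1 peak. A promoter peak is a peak within 2.5 kb of the TSS. For each of 17 gene lists, the median covered length within 50 kb of the TSS was set against 10000 random lists of the same size, drawn from genes in the same of 10 classes of gene length and 3 classes of TSS density. This gave a two-sided permutation p, adjusted over the 17 lists by the Benjamini-Hochberg method. The lists were radial glia and neural progenitors, intermediate progenitors and neurogenesis, cortical glutamatergic neurons, ventral telencephalon and GABAergic neurons, telencephalic patterning, synaptic and general neuronal genes, astrocytes and the oligodendrocyte lineage, microglia, endothelial and mural cells, erythroid cells, regulators of midbrain, hindbrain and spinal cord, Hox genes, liver, heart, skeletal muscle, limb and skeletal mesenchyme, and housekeeping genes. All symbols were found, and Emx2 and Lhx2 stood in both the radial glia and the patterning list.

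Overlap between replicates was the share of a list's peaks with at least 50% of their length under the other list. It was compared with 100 placements of the other list at random on the same chromosomes outside assembly gaps. Peak centres were assigned to promoter, exon, intron or intergenic sequence and compared with 100 placements of the same peaks. Promoters were CpG-rich where the 1 kb around the TSS had a CpG observed-to-expected ratio over 0.6 and a GC fraction over 0.5. Motif matches were counted in the 500 bp around the centres of distal peaks, over 2.5 kb from any annotated protein-coding start. Their comparison was windows 10 kb away, outside every deposited peak, equally distal and matched on GC in steps of 2 percentage points. Shares were compared with two-sided Fisher's exact tests, adjusted over 12 motifs. Intervals are at the 95% level, by normal approximation on the log scale for odds ratios and by 2000 bootstrap draws of genes elsewhere (1000 for chromosome X). Genes and windows are not biological replicates, so these tests describe the tissue pool that was measured.

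The tests, the gene lists, the motifs, the alternatives and the rule for named genes were set before the data were examined, except where stated. The rule took, from each list, the 3 genes with most and the 1 with least covered length within 50 kb, and any gene of a forebrain list without a promoter peak. It added the 10 replicated peaks of highest enrichment with their nearest gene, the 20 genes with most covered length keeping 1 per 100 kb, the 10 largest joined domains, and the Dlx1-Dlx2, Dlx5-Dlx6 and Foxg1 loci. Alternatives were the overlap required, stricter q thresholds, equal peak numbers, the pooled list, each replicate's list alone, other windows and promoter distances, no matching, 1 gene per 100 kb, and other joining distances. Those chosen after seeing the data were peaks covered by at least 50% in both replicates, bases nearest to a gene's own TSS, transcript starts in place of gene ends, autosomal genes only, and matching on promoter class.

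Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pysam 0.24.0 and samtools 1.23.1, with matplotlib 3.10.9 for plots. The procedures were tested on simulated data. Covered length differed by 0 bp from base counting over 1000 regions, and the overlap of 5000 simulated peaks by 0.0618 percentage points from the planted share. Of 300 simulated lists of 14 genes, the gene list test called 5.0% with no effect, 55.3% with a planted 2-fold effect and 98.0% with a 4-fold effect. The motif comparison, in 3373 windows, called the 1 planted motif and 0 others.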

Results

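H3K4me1 peaks were examined in forebrain of mouse embryos at day 16.5, when the cortex holds dividing progenitors and newly made neurons side by side. There was 1 group of 2 biological replicates, each a pool of mixed-sex embryos. Replicate 1's list held 200319 peaks over 94.7 Mb and replicate 2's 106129 peaks over 43.5 Mb. The pooled list held 150400 peaks over 81.0 Mb. The replicated list, used below unless another is named, held 123291 peaks over 74.5 Mb, with a median width of 439 bp and a widest peak of 11722 bp. Read depth was unknown, since the lists carry no counts. Spread between replicates is given, for the gene list medians and the main shares, as the value in each replicate's own list.

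Genes of neural progenitors lay far above matched genes in H3K4me1. Radial glia genes had a median of 12.6 kb of peaks within 50 kb of the TSS (13.9 kb in replicate 1, 7.84 kb in replicate 2), against 1.98 kb in matched random lists, and all 14 had a promoter peak. Among them were Notch1 (29.9 kb), the receptor that holds progenitors undifferentiated, Nes (25.5 kb), the intermediate filament of neural stem cells, and Sox2 (22.5 kb), which maintains progenitor identity. Intermediate progenitor and neurogenesis genes reached 11.7 kb (13.4 and 7.09 kb in the replicates) against 1.58 kb, with promoter peaks at 10 of 10. Here Btg2, an antiproliferative gene of neurogenic divisions, had 22.7 kb, the zinc-finger gene Insm1 had 18.9 kb and the Notch ligand gene Dll1 had 14.3 kb. At the low end, Prom1 had 2.27 kb and the proneural gene Neurod4 had 1.05 kb. For comparison, 63.8% of all genes had a promoter peak, and 97.2% of autosomal genes with CpG-rich promoters. Both medians lay above all 10000 matched random lists (adjusted p = 0.00170 each over 17 lists, permutation; raw p = 0.000200, the smallest that 10000 lists can give). Of the members, 13 of 14 and 9 of 10 lay above the median of their matched genes. The excess was 6.33-fold and 7.40-fold, but 3.63-fold and 3.40-fold without matching, and for intermediate progenitors 2.44-fold with matching also on promoter class (CpG-rich or CpG-poor), chosen after seeing the data; both calls held.

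Genes of both main neuron classes and of telencephalic identity also lay above matched genes. Cortical glutamatergic genes had a median of 8.03 kb (10.9 and 4.46 kb in the replicates) against 2.49 kb, with 13 of 14 promoters marked (raw p = 0.00100, adjusted p = 0.00340, permutation). The highest was Bcl11b at 42.5 kb, a transcription factor of subcortical projection neurons, ranked 9 among 21911 genes. Next came Neurod2, a factor of excitatory neuron differentiation, at 38.7 kb and Slc17a7, a vesicular glutamate transporter, at 16.2 kb. Ventral telencephalon and GABAergic genes had 8.38 kb (9.83 and 4.17 kb) against 2.36 kb, with 15 of 16 promoters marked (raw p = 0.000600, adjusted p = 0.00255, permutation). Slc32a1, the vesicular GABA transporter, had 16.5 kb, while the interneuron genes Dlx1 and Ascl1 had 11.9 kb each and Nkx2-1, a factor of the medial ganglionic eminence, had 2.27 kb. Telencephalic patterning genes had 8.54 kb (11.6 and 5.05 kb) against 1.76 kb, with 11 of 12 promoters marked (raw p = 0.000600, adjusted p = 0.00255, permutation). Emx1 had 19.3 kb, the cortical selector gene Lhx2 16.6 kb, Emx2 13.8 kb and Sp8 the least, 6.49 kb. With matching also on promoter class, the excess fell from 3.55-fold to 2.27-fold for the ventral and from 4.86-fold to 3.02-fold for the patterning list, and both calls held. Without matching on length and density, the cortical glutamatergic and patterning lists no longer passed (2.33-fold and 2.48-fold, adjusted p = 0.0544 each, permutation).

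Genes of later or broader neural functions were nearer to the threshold. Astrocyte and oligodendrocyte lineage genes had a median of 7.56 kb (9.90 and 4.49 kb in the replicates) against 3.12 kb, with 9 of 12 promoters marked (raw p = 0.0114, adjusted p = 0.0277, permutation). Olig1 (16.4 kb) and Olig2 (14.3 kb), the neighbouring regulators of oligodendrocyte precursors, led the list. The myelin gene Mog had 11.9 kb but no promoter peak, and Plp1, a myelin gene on chromosome X, had none within 50 kb. That call, at 2.42-fold, was lost with a window of 10 kb (1.35-fold, adjusted p = 0.638, permutation). It was also lost with 1 gene per 100 kb (11 genes, 2.20-fold, adjusted p = 0.0671, permutation) and without matching (2.21-fold, adjusted p = 0.0897), where the fold stayed near that of the main setting. Synaptic and general neuronal genes had 7.22 kb (8.72 and 3.19 kb) against 3.93 kb, and 12 of 15 promoters were marked, but the list did not pass (raw p = 0.0380, adjusted p = 0.0718, permutation). With matching also on promoter class, chosen after seeing the data, it passed (adjusted p = 0.0391, permutation). Its excess was 1.84-fold at the main settings and 1.70-fold in replicate 1's list (adjusted p = 0.0738, permutation). In replicate 2's list it was 1.43-fold (0.444), and with peaks covered in both replicates 1.37-fold (0.520). Windows of 10 kb and 100 kb gave 1.54-fold (0.199) and 1.41-fold (0.356). The postsynaptic scaffold gene Dlg4 had 24.0 kb, Camk2a 18.4 kb, the NMDA receptor gene Grin1 12.6 kb and Gabrb3 0.919 kb.

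In the replicated list, 6 genes of the forebrain and neuronal lists lacked a promoter peak: Mef2c, Gad1, Nr2f1, Grin2b, Nrxn1 and Gabrb3. Mef2c and Gabrb3 had 1.28 and 0.919 kb of peaks within 50 kb, while Nr2f1, a regulator of cortical area identity, had 11.8 kb and Gad1, the enzyme of GABA synthesis, 6.06 kb. Grin2b had 7.89 kb and Nrxn1 1.5 kb. Each of the 6 had a peak within 2.5 kb of another annotated start of a protein-coding transcript, a count made after seeing the data. The number depended on the replicate. Nr2f1 and Nrxn1 had a promoter peak in replicate 1's own list, while in replicate 2's own list such peaks lay at only 12 of 14 cortical glutamatergic, 14 of 16 ventral, 9 of 12 patterning and 10 of 15 synaptic genes.

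Most lists of other cell types and tissues did not pass the test. Microglial genes had a median of 3.49 kb (4.21 and 2.26 kb in the replicates) against 3.27 kb, with 3 of 12 promoters marked (C1qb 10.02 kb, P2ry12 0.896 kb; adjusted p = 0.892, permutation). Endothelial and mural genes had 2.45 kb (2.60 and 1.64 kb) against 2.89 kb, with 9 of 12 promoters marked (Pdgfrb 8.48 kb, Rgs5 0.186 kb; adjusted p = 0.835, permutation). Erythroid genes had 4.58 kb (5.6 and 3.02 kb) against 4.25 kb, with 5 of 10 promoters marked (Epor 14.02 kb, Alas2 none; adjusted p = 0.892, permutation). Liver genes had 2.24 kb (2.99 and 1.38 kb) against 3.6 kb, with 3 of 14 promoters marked (Tat 5.6 kb, Afp none; adjusted p = 0.373, permutation). Heart genes had 4.87 kb (5.6 and 2.81 kb) against 3.01 kb (Myh7 9.26 kb, Actc1 2.23 kb; 7 of 12 promoters; adjusted p = 0.373, permutation), with 12 of 12 members above the median of their matched genes. Limb and skeletal mesenchyme genes had 5.0 kb (6.24 and 3.15 kb) against 2.80 kb (Col2a1 14.7 kb, Runx2 0.893 kb; 11 of 12 promoters; adjusted p = 0.184, permutation). Hox genes had 4.84 kb (5.61 and 3.01 kb) against 5.43 kb (Hoxd9 8.17 kb, Hoxb2 0.534 kb; 8 of 15 promoters; adjusted p = 0.881, permutation). Midbrain, hindbrain and spinal cord regulators had 5.64 kb (6.59 and 3.42 kb) against 2.05 kb (Pax7 9.36 kb, Hoxb1 1.13 kb; 10 of 12 promoters; raw p = 0.0284, adjusted p = 0.0603, permutation), with 11 of 12 members above. Housekeeping genes had 6.47 kb (8.90 and 4.01 kb) against 3.89 kb and promoter peaks at 18 of 18 (Vcp 17.5 kb, Hprt, on chromosome X, 0.535 kb; adjusted p = 0.177, permutation). With matching also on promoter class, the liver list went from 0.622-fold to 1.05-fold and the microglial list from 1.07-fold to 2.36-fold, and neither passed (adjusted p = 0.960 and 0.274, permutation). The direction for liver thus changed with matching on promoter class, while it was 0.647-fold without any matching. Direction also moved with the setting for Hox genes and for endothelial and mural genes, and neither list passed. Hox genes were at 0.891-fold, and 0.898-fold with a window of 100 kb, but 1.60-fold with 10 kb and 1.42-fold without matching. Endothelial and mural genes were at 0.848-fold, and 0.702-fold without matching, but 1.16-fold with 10 kb and 1.21-fold with peaks covered in both replicates. Several calls depended on the setting. Midbrain, hindbrain and spinal cord regulators passed with a window of 10 kb (adjusted p = 0.0248, permutation), with only bases nearest to each gene's own TSS (0.0170) and with peaks covered in both replicates (0.0466). Their excess fell from 2.75-fold to 1.60-fold with matching also on promoter class (adjusted p = 0.274, permutation) and to 1.64-fold without matching (0.377). Housekeeping genes passed with a window of 10 kb (adjusted p = 0.00567, permutation), with own-TSS bases (0.0160) and in replicate 1's list alone (0.0472), and limb and skeletal mesenchyme genes with own-TSS bases (0.0465).

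Skeletal muscle genes were the only list of another tissue to pass at the main settings. Their median was 7.58 kb (9.21 and 4.14 kb in the replicates) against 2.75 kb, with 8 of 12 promoters marked and 8 of 12 members above the median of their matched genes (raw p = 0.00900, adjusted p = 0.0255, permutation). The excess was 2.75-fold, as for the midbrain, hindbrain and spinal cord list. Mylpf, a myosin light chain gene, had 12.3 kb, the intermediate filament gene Des 11.3 kb, the myogenic regulator Myod1 11.3 kb and Myf6 0.517 kb. The call was lost with own-TSS bases (1.71 kb against 0.742 kb, 2.31-fold, adjusted p = 0.192, permutation) and with peaks covered in both replicates (2.51-fold, adjusted p = 0.0929), where the fold stayed near that of the main setting. It was also lost with a window of 10 kb (1.70-fold, adjusted p = 0.594, permutation) and without matching (2.20-fold, adjusted p = 0.0897). Over all 17 lists, 7 lay above matched genes and 0 below, with 7 above in replicate 2's list and 8 in replicate 1's, and with own-TSS bases 9 lay above, 6 of them among these 7.

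**Figure D1:**
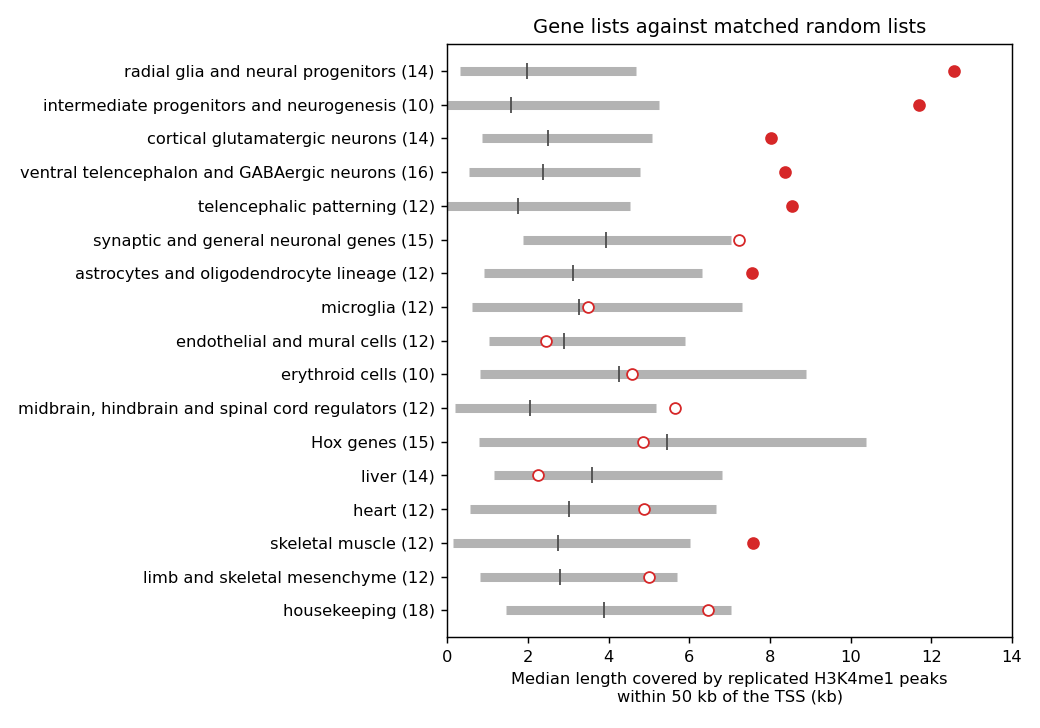
Median length covered by replicated H3K4me1 peaks within 50 kb of the TSS, in kb, for the 17 gene lists, with the number of genes in parentheses. Grey bars show the range of 95% of matched random lists, ticks their median, and filled points the lists with an adjusted p under 0.05; radial glia genes lie at 12.6 kb and liver genes at 2.24 kb.

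Across the whole genome, the 20 genes with most covered length, 1 per 100 kb, ranged from 33.7 to 54.9 kb, against a median of 3.42 kb over all genes. The first was G430095P16Rik at 54.9 kb, which lies within Nfix, a nuclear factor I gene of neural differentiation with 46.7 kb within 50 kb of its TSS. Next were Pipox at 53.9 kb, beside Sez6, Ncor2 at 50.2 kb, a nuclear receptor corepressor gene, Flrt1 at 47.8 kb and Tcf20 at 42.8 kb. Bcl11b, Lrp8 (40.9 kb), which encodes a reelin receptor, Foxo6 (39.9 kb), Neurod2 and Bcl11a (38.2 kb), a factor of cortical projection neurons, followed. The others were Nr1d1, Map4k4, Thtpa, Zmiz1, Stra6, Pmepa1, Ssbp3, Bahcc1, Rara and Ahdc1, at 33.7 to 37.9 kb. The 50 kb windows of neighbouring genes overlap, so the same peaks can count for several genes, as at Nr1d1, which has Casc3, Med24, Msl1 and Thra within 50 kb.

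Peaks within 3 kb of each other formed 60027 domains. The largest overlapped Gse1 and the annotated gene Gm20388 on chromosome 8, from 120483698 to 120567158, with 70.5 kb under peaks (71.2 kb in replicate 1, 57.4 kb in replicate 2). The domain in Bcl11b, on chromosome 12 from 107946813 to 108000055, held 44.1 kb and ended 3547 bp inside the gene. The Nfib domain on chromosome 4, from 82425951 to 82501150, held 38.7 kb and lay 204600 bp from the 5′ end of this nuclear factor I gene. Its distance to other annotated starts of Nfib was not measured. The remaining 7 of the 10 largest overlapped Ttc28 (45.4 kb), Ncor2 (44.9 kb), Map4k4 (44.4 kb), Foxo6 (37.3 kb), Bcl11a (36.0 kb), Lrp8 (34.5 kb) and Pbx1 (34.5 kb), a homeodomain gene. Sizes and order moved with the joining distance. With 1 kb the largest domain was in Bcl11b (36.3 kb, against 35.96 kb in Gse1), and with the widest distance tried it was again at Gse1 (167.0 kb). The 10 largest domains under these settings overlapped 4 and 3 of the 10 named here.

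**Figure D2:**
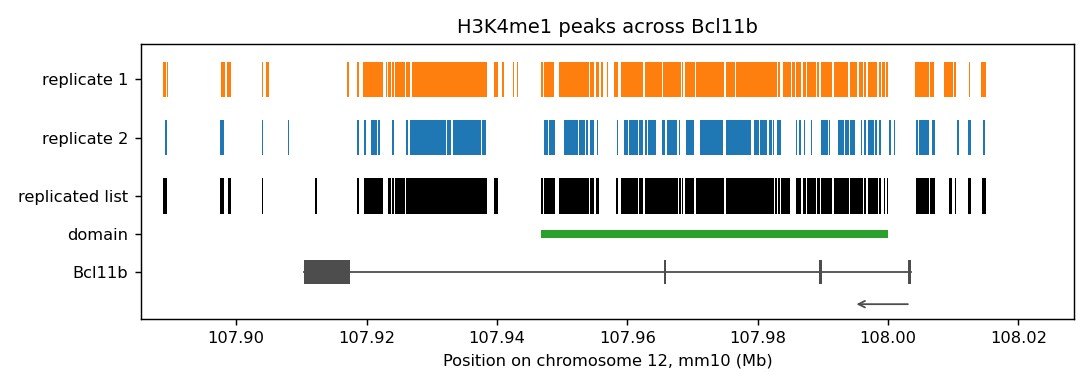
Peaks of each replicate and of the replicated list across Bcl11b on chromosome 12, position in Mb on mm10. Boxes on the lowest track are exons, the line between them introns, the arrow the direction of transcription, and the green bar the joined domain with 44.1 kb under peaks.

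The 10 replicated peaks with the authors' highest enrichment lay mainly in introns or between genes. Enrichment reached 15.4 in an intron of Ncor2 (chromosome 5, 125150435 to 125161094), 18.1 kb from its TSS. It was 14.8 in an intron of Mprip (chromosome 11, 59707035 to 59708737) and 14.4 in an intron of Ttc28 (chromosome 5, 111121971 to 111124356). Intergenic peaks had Lrrc74a (14.7), Irf2bp2 (13.8) and Cstad (13.8) as nearest genes, at 65.5, 72.7 and 50.5 kb. Promoters of Cyth2 (13.9), Vcpip1 (13.7) and Fam92b (13.7) and an intron of Ulk1 (13.9) made up the rest. Each of the 10 was covered by at least 94.1% in replicate 1 and 75.0% in replicate 2.

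At the Dlx genes, which direct GABAergic neuron development, peaks lay over the promoters and in the sequence between each gene pair. Within 10 kb of Dlx1 and Dlx2 (chromosome 2, 71528113 to 71546754) there were 15 replicated peaks over 8010 bp, 5 of them between the genes. The strongest was one of these, at 71540985 to 71541777, with an enrichment of 6.43 and 73.4% of its length in replicate 2. At Dlx5 and Dlx6 (chromosome 6, 6863334 to 6882085) there were 14 peaks over 7155 bp, 3 of them between the genes, and the strongest lay over the Dlx5 promoter at 6880965 to 6881893 (7.48). Foxg1, the forkhead gene required for telencephalon growth (chromosome 12, 49382660 to 49386861), carried 0 peaks within the gene and 7 beside it. The nearest, 2.23 kb from the TSS, spanned 49379974 to 49380426. At least 50% of the length was under peaks of both replicates for 2 of the 15, 5 of the 14 and 5 of the 7 peaks.

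H3K4me1 peaks were concentrated at promoters and in introns and were sparse between genes. Of peak centres, 25.9% lay within 2.5 kb of a TSS, 4.32-fold the share of random placements. Introns held 41.4% (1.20-fold) and intergenic sequence 29.8% (0.526-fold). All 100 placements lay below the observed share for promoters and introns and above it for intergenic sequence. Exons held 2.99% against 2.86% in placements, a 1.04-fold difference that all placements stayed under but that did not hold with peaks covered in both replicates (0.996-fold). Promoter enrichment was 3.51-fold in replicate 1's list and 4.77-fold in replicate 2's.

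Promoters of the CpG-rich class, typical of broadly used and developmental genes, were flanked by H3K4me1 on both sides of the TSS. Of 9718 genes with CpG-rich promoters, 97.1% had a peak within 5 kb, against 42.9% of 12186 with CpG-poor promoters. Coverage of the CpG-rich class was highest 1000 bp downstream, where 58.4% of genes were covered, with a second rise to 40.1% at 600 bp upstream. At the TSS itself only 11.8% were covered, less than the 14.5% of CpG-poor promoters (Fisher's exact test, two-sided, p = 1.59e-08). Downstream by 1.5 kb the order turned, with 48.1% against 10.2% (odds ratio 8.14, p too small for the software to represent). In replicate 1 the shares at the TSS were 13.0% and 15.8%, and in replicate 2 they were 6.79% and 8.73%.

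**Figure D3:**
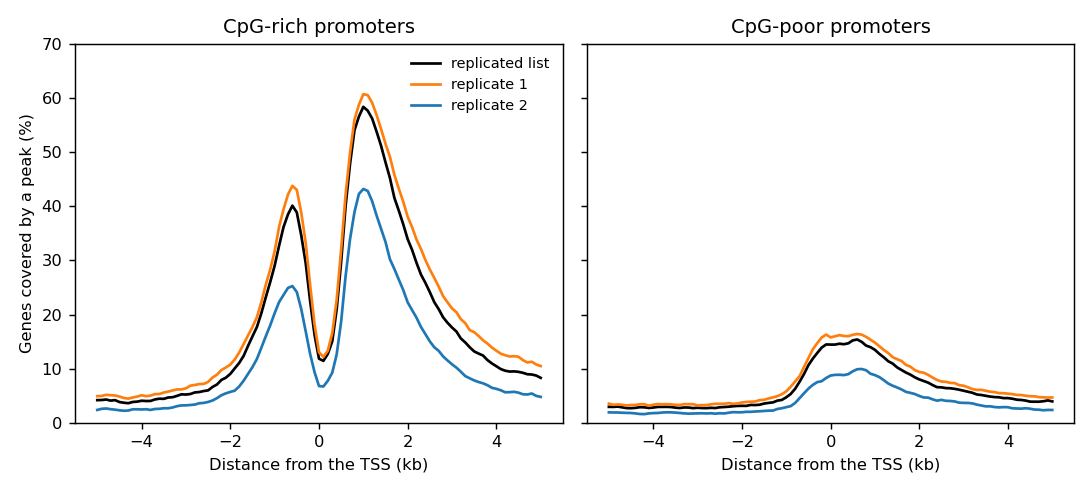
Percentage of genes covered by an H3K4me1 peak at each distance from the TSS, in kb, for genes with CpG-rich and CpG-poor promoters, in the replicated list and in each replicate's list. Lines for CpG-rich promoters rise on both sides of the TSS, to 58.4% downstream in the replicated list, and fall to 11.8% at the TSS.

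Distal peaks were enriched for the binding sequences of several transcription factor families of the developing forebrain. The nuclear factor I palindrome TTGGCNNNNNGCCAA occurred in 165 of 82179 peak windows and in 17 matched windows (odds ratio 9.72, 95% interval 5.79 to 15.5, adjusted p = 2.00e-31, Fisher's exact test), with odds ratios of 6.39 in replicate 1's own list and 8.08 in replicate 2's. The RFX site GTTGCCATGG, part of the X-box, was in 0.857% against 0.223% (odds ratio 3.87, interval 3.28 to 4.55). The POU octamer ATGCAAAT was in 5.06% against 2.52% (2.07, interval 1.958 to 2.18), the homeodomain core TAATTA in 18.2% against 10.05% (1.99, interval 1.93 to 2.04), and the MEF2 element CTAWWWWTAG in 1.30% against 0.691% (1.90, interval 1.71 to 2.10). The proneural E-box CAGATG was in 40.2% against 36.3% (1.18, interval 1.16 to 1.21) and the SOX site ACAATGG in 7.78% against 7.34% (1.07, interval 1.03 to 1.11). These last 2 ratios lay inside the range of 10 shuffled sequences of the same letters, up to 1.27 and 1.21, a comparison added after seeing the data.

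Of the 5 comparison motifs, mostly of factors of other tissues, only the CTCF site passed as more frequent in distal peaks. The CTCF site CCASYAGRKGGC, bound by the widely present insulator protein, was in 0.774% against 0.333% (odds ratio 2.33, interval 2.02 to 2.68). With the whole peak in place of 500 bp, this call was lost (1.12, adjusted p = 0.203, Fisher's exact test). The hepatocyte HNF4 site CAAAGTCCA was less frequent in peaks, 0.634% against 0.789% (0.803, interval 0.715 to 0.901), as was the erythroid GATA site AGATAAG (0.939, interval 0.902 to 0.978), though the GATA ratio lay inside the range of its shuffled sequences (0.840 to 1.17). The HNF4 ratio lay only just under the lowest of its 10 shuffled sequences, 0.807. The ETS site CCGGAAGT did not differ past the threshold (0.909, interval 0.787 to 1.05, adjusted p = 0.229, Fisher's exact test), though its ratio lay below all 10 of its shuffled sequences (1.03 to 1.85). The HNF1 site occurred in 1 peak window and 2 matched windows. Of 12 motifs, 8 were more frequent and 2 less frequent, with adjusted p at most 0.00294, Fisher's exact test, and the SOX call was lost in replicate 1's list alone (adjusted p = 0.150).

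Olfactory receptor genes, a large family used in the nasal epithelium, almost all lacked a called H3K4me1 peak at their promoter. Only 5 of 1134 had a promoter peak (0.441%), against 67.2% of 20777 other protein-coding genes (odds ratio 0.00216, Fisher's exact test, p too small for the software to represent). The 5 were Olfr1331, Olfr325, Olfr459, Olfr550 and Olfr95, named after their values were seen. In the replicates' own lists the shares were 0.794% and 0.529%. The other genes were not matched on promoter class, and of all genes with CpG-poor promoters 42.9% had a peak within 5 kb. Many of the receptor genes lie close together, and the test treated them as independent. Kept at 1 per 100 kb, 279 remained, with a promoter peak at 0.358%.

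Chromosome X carried far less H3K4me1 than any autosome. Peaks covered 3.21 kb per Mb of X, against an autosomal median of 31.6 kb and a range from 22.4 kb on chromosome 3 to 46.9 kb on chromosome 11. Gene density did not set X apart, at 5.80 genes per Mb against 5.50 on chromosome 12 and 5.83 on chromosome 18. The ratio of X to the autosomal median was 0.101, with 0.139 in replicate 1 and 0.0795 in replicate 2. Neuronal genes on X still had peaks, with 9.34 kb within 50 kb of Dcx, a gene of migrating neurons, 4.22 kb at the interneuron gene Arx and 1.94 kb at Syn1, named here because they are the X-linked members of the neuronal lists. In replicate 2's own list none of these 3 had a promoter peak. No test was planned for this comparison.

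**Figure D4:**
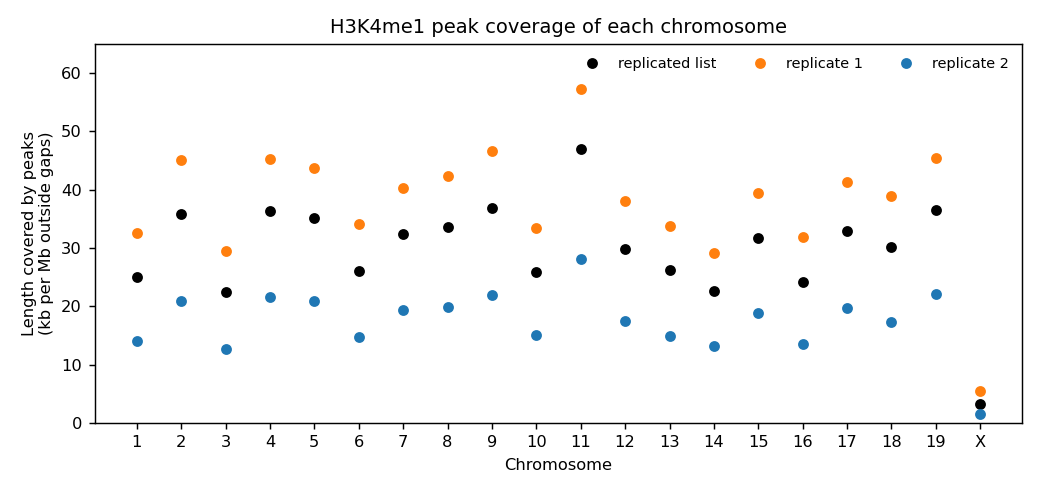
Length covered by H3K4me1 peaks in kb per Mb of each chromosome outside assembly gaps, for the replicated list and each replicate's list. X lies at 3.21 kb per Mb in the replicated list, below the lowest autosome, chromosome 3, at 22.4.

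Most peaks of replicate 2 were found in replicate 1, but not the reverse. Of replicate 2's peaks, 86.1% had at least 50% of their length under replicate 1's peaks, against a mean of 3.62% and a highest of 3.73% in 100 random placements. Of replicate 1's peaks, 28.9% lay in replicate 2 (placements 1.57%, highest 1.65%). The shares were 65.1% and 5.75% with 90% of the length required, and 73.7% and 44.6% with equal numbers of peaks. Both covered 37.9 Mb, which was 87.2% of replicate 2's covered length and 40.0% of replicate 1's. Replicate 1 held 1.89 times as many peaks over 2.18 times the length. The share also depended on rank: 82.8% of replicate 1's strongest 20032 peaks by p lay in replicate 2, and 7.61% of its weakest 20031. For replicate 2, the strongest 10613 peaks reached 99.7% and the weakest 10612 reached 72.7%.

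**Figure D5:**
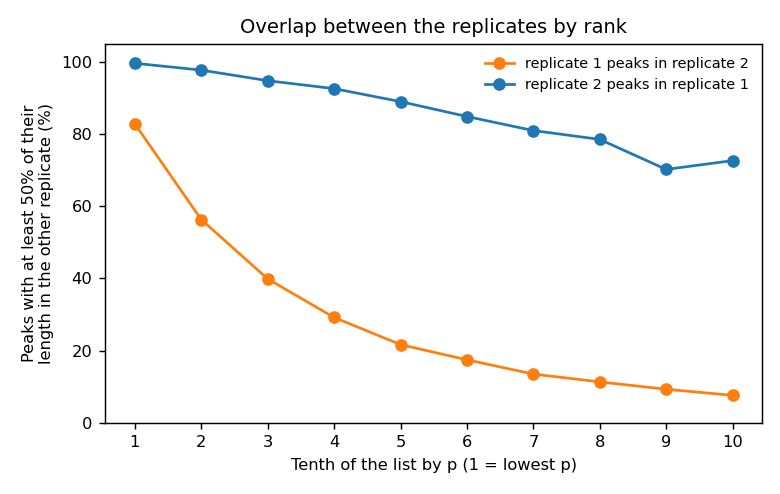
Percentage of peaks with at least 50% of their length in the other replicate, for 10 equal classes of each replicate's peaks by p, from the lowest p on the left. Replicate 1 falls from 82.8% to 7.61%, and replicate 2 lies between 70.2% and 99.7%.

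The replicated list was a subset of the pooled list rather than a list of peaks found in each replicate. All 123291 replicated peaks were identical to pooled peaks and made up 82.0% of them. By the 50% criterion 49.6% of replicated peaks were covered in both replicates, 45.0% in replicate 1 alone, 3.0% in replicate 2 alone and 2.39% in neither. Only 3 of the 27109 pooled peaks left out were covered in both. With at least 1 shared base, 63.2% were covered in both replicates, and with 90%, 6.12%.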

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

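Settings with peaks covered in both replicates, own-TSS bases, autosomal genes or matching on promoter class were chosen after the results were seen. Of 62 values of the comparisons under the settings fixed beforehand, 56 were counted as unchanged, 2 as weaker and 4 as moved. Of 13 under settings added later, 11 were counted as unchanged. For tests and placements, unchanged meant the same side of the threshold or placements. For numbers of gene lists or motifs it meant only a similar count. With a window of 10 kb, 7 lists lay above, but only 5 of them were among the 7 of the main setting. The number of gene lists above matched genes was 3 without matching, in place of 7, and the cause was not tested. The exon fold was 1.04 with q at most 0.01, where the highest placement exceeded the observed share, and 0.996 with peaks covered in both replicates; the cause was not tested. The largest domain held 36.3 kb with joining within 1 kb and 167.0 kb with the widest joining, and the share of replicated peaks covered in both replicates was 63.2% with 1 shared base and 6.12% with 90%, by construction of these settings. With peaks covered in both replicates, 1 motif in place of 2 was less frequent in distal peaks, since GATA no longer passed (odds ratio 0.947, adjusted p = 0.100, Fisher's exact test). In the lists of single replicates, 7 to 8 gene lists lay above, 7 to 8 motifs were more frequent, promoter folds were 3.51 to 4.77, and the ratio of X to autosomes was 0.0795 to 0.139. Of 136 medians of single gene lists under planned settings, 126 kept their call, 7 lost it and 3 gained it. No paired analysis was possible because the labels give 1 group. Read depth is unknown, so a missing peak, above all in replicate 2, does not show that the mark was absent.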

Other observations

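The scan of gene families, the comparison of muscle promoters, the folds of the muscle list and the counts of own-TSS bases were chosen after the results were seen. Comparisons of CpG-rich windows away from starts and of length missing from replicate 2 were also outside the tests set beforehand. So were those of repeats, promoters and peak strength on chromosome X. They addressed patterns already seen in the data. Among 297 families of genes sharing the start of their symbol, each with at least 8 genes, 8 lay above matched genes and 7 below (permutation, adjusted over the 297). The matching was on gene length and TSS density and not on promoter class. Of genes kept at 1 per 100 kb, 70.8% to 100% had a promoter peak in families above, and 0% to 27.3% in families below. Whether these calls would hold with matching on promoter class was not tested. Sox genes, transcription factors of development, had a median of 7.90 kb of H3K4me1 within 50 kb of the TSS against 1.92 kb, with a promoter peak at 100% of 19 genes (adjusted p = 0.0119, permutation). Srsf genes, which encode splicing factors, had 11.1 kb against 3.36 kb (adjusted p = 0.0228, permutation), and Sema genes, many of them axon guidance cues, 9.35 kb against 3.91 kb (adjusted p = 0.0228). Ribosomal protein genes lay above as well, with 6.93 kb for Rps and 6.16 kb for Rpl, as did the Bcl, Tmem and Fam symbols, which group unrelated genes. Cyp genes, cytochromes P450 of metabolism, had 0.240 kb against 2.69 kb (adjusted p = 0.0119, permutation). The Olfr, Vmn, Nlrp, Skint and Sult families had a median of 0, and Tmprss genes had 0.855 kb.

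CpG-rich windows away from annotated transcript starts did not show the dip seen at CpG-rich promoters. Of 1945 windows over 5 kb from any such start, inside or outside genes, 14.4% were covered at the centre and 4.63% and 4.83% at 1.5 kb on either side, and against the first of these flanks 227 windows were covered at the centre alone and 37 at the flank alone (exact binomial p = 1.65e-34).

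Chromosome X held 0.101 of the autosomal median of covered length per Mb, and sequence masked as repeats does not account for this. Whether reads could be placed in the remaining sequence was not measured. Per Mb of unmasked sequence X had 5.36 kb, against an autosomal median of 41.7 kb and 30.8 kb on the lowest autosome. The ratio of X to that lowest autosome, rather than to the median, was 0.174 (0.229 and 0.143 in the replicates). Fewer marked genes are part of the pattern, with a promoter peak at 70.8% of CpG-rich genes on X and 97.2% on autosomes (86.3% and 98.2% in replicate 1, 56.6% and 94.3% in replicate 2). They are not the whole of it, since X genes with such a peak had 0.231 of the covered length of their autosomal counterparts (95% interval 0.182 to 0.297), and 0.354 with own-TSS bases (0.292 to 0.395). Strong peaks were the most depleted, with the X-to-autosome ratio in the strongest 10% of replicate 1's peaks 0.0705 of that in the weakest 10%, as a weaker signal along all of X may produce. Fewer copies of X in a mixed-sex pool and an inactive X in female cells both predict a weaker signal on X. How large a deficit in covered length or in strong peaks either would give was not tested. These explanations were not told apart here and stay open.

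Replicate 1 held many peaks that replicate 2 lacked. Cells of another tissue in replicate 1 would leave an excess at genes of that tissue. The genes examined were those of the liver, heart, skeletal muscle, limb and skeletal mesenchyme, and Hox lists, pooled as 65 genes. There, replicate 2 lacked only 3.20 percentage points more of replicate 1's covered length than at all genes (95% interval −0.288 to 6.73). At forebrain genes it lacked 5.51 points more (1.54 to 9.54). No list was examined singly, so an excess confined to 1 tissue could be diluted in the pooled genes, and the values do not exclude it. The erythroid, endothelial, microglial and midbrain, hindbrain and spinal cord lists were not examined, so the values do not address such cells. Lower sensitivity in replicate 2 may account for part, since 82.8% of the strongest 10% of replicate 1's peaks lay in replicate 2. With equal numbers of peaks, however, the shares still differed by 29.1 percentage points, and replicate 1's strongest peaks were wider, so the test leaves this open. No biological explanation was tested.

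Skeletal muscle genes stood above matched genes in this forebrain tissue. Peaks of neighbouring genes stay open: with own-TSS bases the call was lost, but the excess was 2.31-fold (1.71 kb against 0.742 kb, 95% of random lists from 0 to 2.04 kb) and 2.75-fold before (7.58 kb against 2.75 kb, 0.141 to 6.02 kb). The fold was lower and the random lists spread more widely relative to their median, and which of these ended the call was not tested. Muscle cells in the tissue stay open too, since 66.7% of the members had a promoter peak, between the median of 50% in random lists and the upper end, 75%, of the range of 95% of them. No biological explanation was tested.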
